A study of Mus musculus with 12 samples.

How the data were processed

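RNA was measured in 12 mouse liver libraries that fall into 4 groups of 3: normal liver and liver tumors, each from wild-type (WT) mice and from mice labelled as Setd2 knockout (KO). Sample titles call the latter cKO, an abbreviation usually read as conditional knockout, but the labels do not spell it out or name the cells in which the gene was deleted. Setd2 encodes the methyltransferase that places the trimethyl mark on lysine 36 of histone H3. Per the labels' protocols, normal liver came from male mice aged 8 months without diethylnitrosamine (DEN), a liver carcinogen. Tumors came from mice given 1 dose of DEN at 25 mg/kg at 2 weeks of age and taken after 8 months. RNA was extracted with a spin-column kit, polyadenylated RNA was selected on beads, and the libraries were built with a kit that does not keep the strand, per the labels' protocols.

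The authors deposited 1 table per library with a gene name and an FPKM value (fragments per kilobase of transcript, scaled to the mapped fragments) in each line. Per the submitters' processing notes, TopHat2 2.1.1 and Cufflinks 2.2.1 made these values on genome build mm10. Program options and the gene annotation are not given in the sources used here. Each table held 24553 entries under 23688 different names, of which 865 repeated a name and 600 joined several gene names. Repeated names were kept apart as entries of their own, because the tables give no position for them. They were numbered by mean FPKM from the highest, so Scd1#2 ranks next below the entry that kept the bare name. Total reads are not in the files, so the depth behind each value is unknown and no counting error can be given. Steps between low values did not reveal whole reads, since at most 4.22% of low values in a library fell on a common ratio.

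The values were analyzed as log2(FPKM + 1). An entry was tested when it reached an FPKM of 1 in at least 3 of the 12 libraries, which left 11671 entries, called genes from here on. Each comparison of 2 groups was fitted on its own 6 libraries with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a trend of the variance with the mean. The difference of the KO effect between tumor and normal liver was fitted as an interaction on all 12 libraries. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 11671 genes, and a gene was called at an adjusted p below 0.05. The added 1 shrinks changes of genes with low FPKM, so their log2 fold changes understate the ratio of the FPKM values. P-values measure the spread between these samples, and the labels do not state outright that each library came from its own animal.

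Gene lists were fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and the alternatives, except where later choices are pointed out. The 35 lists hold 797 symbols, of which 728 matched an entry of their own and 44 an entry shared with other genes. They cover lipid and cholesterol metabolism, hepatocyte functions and zonation, sex-biased liver genes, cancer markers, cell cycle and stress programs, enzymes of H3K36 methylation, and markers of other cell types. A list was tested with camera, from limma, at its preset correlation of 0.01 between genes, when 5 or more members were tested, and p-values were adjusted over the 32 lists that qualified. B and plasma cell markers had 3 tested members, adipose and skeletal muscle genes 3, and exocrine pancreas genes 0. The list tests were repeated with a correlation estimated from the data and with fry, a rotation test of each list on its own.

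Genes were named by a rule. Setd2 was named in every library. In each comparison of 2 groups the rule took up to 8 called genes with the largest rise and 8 with the largest fall. Their groups had to be fully separated, and the higher group needed a mean FPKM of 5 or more. For the interaction it took up to 5 each way. For each list described it took up to 4 members with the smallest adjusted p, passing or not, and a fixed set of textbook genes. Unnamed gene models and small RNAs were left out. Some genes that the rule names are not reported in the text, for reasons that do not depend on their values, and they stay in every count and list test.

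Alternatives were pseudocounts of 0.1 and 5, no filter on low FPKM, a filter of mean FPKM 5, and rescaling of each library to a common sum (TPM). Others were median-of-ratios scaling, quantile normalization, 1 fit of all 12 libraries, array quality weights, no variance trend, the replicate number as a block, and leaving out each library in turn. Chosen after the data were seen were the treatment of improbable zeros as missing, a restriction to entries with 1 gene name found once, and removal of each library's trend with transcript length. Genes were matched by name to GENCODE vM21 on GRCm38, the assembly that mm10 names, which placed 10373 of the 11671 tested entries (88.9%). All coordinates come from that match.

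The fits were tested on simulated data for the 11671 genes, with 100 genes changed by each fold size. Values were drawn from a normal distribution around each gene's mean, with the moderated SD of the fit in every group. The real KO tumors spread more than WT tumors (median SD 0.306 and 0.188), and outlying libraries were not simulated. Recovery in the real data may therefore differ. In normal liver, KO against WT, 82% of 2-fold and 98% of 4-fold changes were recovered, and in tumor 24% and 80%. Tumor against normal liver gave 85% and 99% in WT and 30% and 92% in KO. The interaction gave 20% and 84%. Between 4 and 13 unchanged genes were called in each simulation. A simulated list of 25 genes shifted by 0.5 on the log2 scale was called each time, with 0 calls among the other lists. Each gene was drawn independently of the others, so this does not show how often lists of correlated genes are called falsely. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.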

Results

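Gene expression was measured in 12 liver libraries, 3 from WT normal liver, 3 from KO normal liver, 3 from WT tumors and 3 from KO tumors. FPKM values of a library summed to between 423498 (KO tumor 1) and 719538 (KO liver 1), and 10233 to 11620 entries per library reached an FPKM of 1. Sequencing depth is unknown. Libraries of a group resembled each other least among KO tumors, where Pearson's r across genes was 0.924 to 0.942 and the median SD was 0.31 on the log2 scale. The median SD was 0.16 in WT liver, 0.17 in KO liver and 0.19 in WT tumors. Means below are FPKM ± SD (n = 3), and changes are log2 differences ± SE from limma. Of the 77 list calls below, 1 held when the correlation between genes was estimated, that of the interferon response list between KO and WT tumors.

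Some abundant liver genes are listed at values that cannot be taken at face value. Alb, the gene of serum albumin, is listed at 0 in 11 libraries and at 14256 in KO tumor 2, and Gapdh, a glycolytic enzyme gene, lies between 0 and 1.34 in all 12. WT tumor 1 alone has 0 for Serpina1b, Serpina1e, Dnajb11, Ahsg and Trf, which exceed 40 in the other libraries. Entries of the major urinary protein genes (Mup) share sequence, and 3 of them have zeros in 1 to 3 normal liver libraries. Albumin and Gapdh therefore give no information here, and values of single Mup genes are uncertain.

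Setd2 (chromosome 9, 110532597 to 110618633, GRCm38) was lower in KO normal liver. Its FPKM was 4.84, 3.84 and 4.70 in the WT livers and 1.66, 1.93 and 1.32 in the KO livers, a fall by 1.05 ± 0.14 (adjusted p = 0.0108). In tumors it was 4.40, 3.61 and 4.07 in WT and 3.14, 2.18 and 1.90 in KO. This difference of -0.57 ± 0.19 did not pass the test (adjusted p = 0.188), although every KO tumor lay below every WT tumor, a separation that chance gives in 10% of genes. The KO effects in both tissues were not shown to differ (0.48 ± 0.23, adjusted p = 0.241). The labels name neither the deleted exons nor the cells that lost them, and an FPKM over the whole gene in tissue also counts reads outside these exons and from cells that kept the gene.

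**Figure D1:**
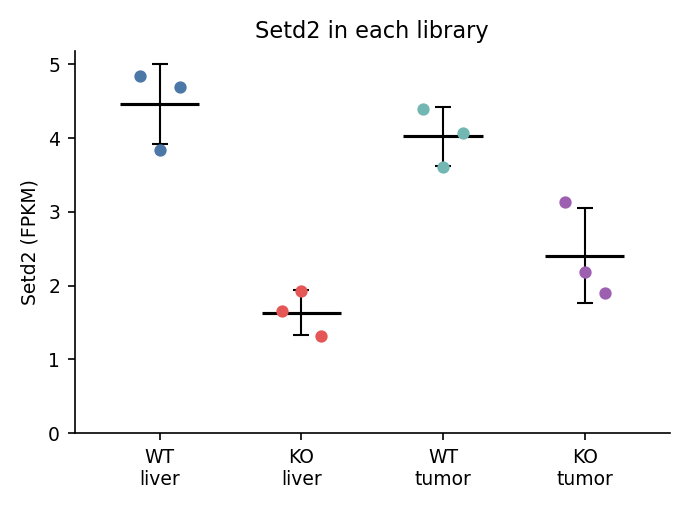
Setd2 FPKM (vertical axis) in each of the 12 libraries by group. Points are libraries, bars are means and error bars are SD (n = 3). KO livers lie between 1.32 and 1.93, below the WT livers at 3.84 to 4.84, and KO tumors lie between 1.90 and 3.14.

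The comparison of KO with WT normal liver asks what the loss of Setd2 changes before any carcinogen. Afp, the fetal serum protein alpha-fetoprotein, rose from 1.95 ± 0.56 to 28.2 ± 12.2 (change 3.25 ± 0.29). G6pdx, which opens the oxidative pentose phosphate pathway, rose from 2.44 ± 0.36 to 23.0 ± 9.04 (2.72 ± 0.30). The membrane protease gene Prss8 rose from 1.33 ± 0.39 to 22.5 ± 5.29 (3.32 ± 0.21) and the adhesion receptor gene Adgrv1 from 1.52 ± 0.63 to 35.4 ± 16.6 (3.78 ± 0.33). Among falling genes, Tnfrsf12a, the receptor of the cytokine TWEAK, went from 100.2 ± 59.3 to 8.73 ± 1.68 (-3.24 ± 0.38). Slc10a2, a sodium-dependent bile acid transporter, went from 50.5 ± 22.0 to 5.08 ± 4.20 (-3.23 ± 0.51), and Cxcl1, a chemokine that draws neutrophils, from 163 ± 90.6 to 20.5 ± 19.9 (-3.22 ± 0.77).

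The remaining genes with the largest rises were Parp16 (2.95), Barx2 (2.62) and the second entries of Serinc1 (4.15) and Scd1 (3.63), a fatty acid desaturase. Scd1 itself, at 907 ± 453 and 1363 ± 798, did not pass (0.49 ± 0.54, adjusted p = 0.538). The remaining largest falls were Mup9 (-4.43), Mup5 (-2.93), Srxn1 (-2.90), Ppl (-2.76) and an entry that joins Cxcl1 and Cxcl15 (-2.81). Adjusted p for the 16 genes ran from 0.00179 for Mup5 to 0.0345 for Cxcl1.

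The cholesterol synthesis list ranked lower in KO normal liver. Of 23 members tested 9 fell and 0 rose, and 11 fell when adjusted over the list alone. Idi1, which makes dimethylallyl diphosphate, fell from 33.9 ± 4.47 to 8.14 ± 1.91 (-1.95 ± 0.18), and Sqle, the squalene epoxidase, from 61.7 ± 9.18 to 17.1 ± 5.75 (-1.84 ± 0.26). Hsd17b7, which acts in the later steps, fell too (-1.36). The list's median was -0.62 (camera adjusted p = 0.00037, adjusted p = 0.727 with an estimated correlation).

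Stress programs ranked lower as well. For the unfolded protein response, 13 of 24 members fell and 2 rose (18 and 2 adjusted over the list alone), with a median of -0.72 (camera adjusted p = 1.84e-05, adjusted p = 0.675 with an estimated correlation). Hspa5, the main chaperone of the endoplasmic reticulum, fell from 1437 ± 240 to 516 ± 60.5 (-1.47 ± 0.16), and its partner Dnajb9 (-1.48 ± 0.10), Herpud1 (-1.57 ± 0.22) and Creld2 (-2.03 ± 0.29) fell alike. Of 22 acute phase genes 3 fell and 0 rose (7 and 0 adjusted over the list alone; median -0.76, camera adjusted p = 0.000384, 0.808 as adjusted p with an estimated correlation). They were Socs3, the feedback inhibitor of cytokine signaling, from 25.7 ± 6.38 to 3.41 ± 1.78 (-2.67 ± 0.33), Orm3 (-2.11) and Serpina3m (-1.23). Of 18 AP-1 and immediate early genes 5 fell and 0 rose (8 and 1 adjusted over the list alone; median -0.89, camera adjusted p = 0.00199, 0.675 as adjusted p with an estimated correlation). Junb fell from 88.7 ± 26.2 to 21.5 ± 8.37 (-2.02 ± 0.32), and Jun (-1.60), Klf6 (-1.22), Fosl2 (-1.0) and Atf3 (-0.67) followed. KO and WT livers overlapped for the acute phase response, where mean log2(FPKM + 1) minus that of WT liver was -0.43, -1.74 and -2.03 in KO livers 1, 2 and 3 and -0.98, 0.30 and 0.68 in WT livers 1, 2 and 3. Without WT liver 1 the median was -1.17 for this list and -0.55 for AP-1 and immediate early genes.

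Hepatocyte identity genes ranked lower, with 8 of 27 falling and 1 rising (9 and 1 adjusted over the list alone; median -0.40, camera adjusted p = 0.00212, 0.675 as adjusted p with an estimated correlation). The transcription factor genes Hnf4a (279 ± 39.1 to 151 ± 28.2, -0.89 ± 0.17) and Nr5a2 (-0.54 ± 0.11) fell, as did Fga, a fibrinogen chain (-1.40 ± 0.29). Oncofetal and liver cancer markers ranked higher, with 4 of 23 rising and 0 falling (5 and 0 adjusted over the list alone; median 0.36, camera adjusted p = 7e-04, 0.675 as adjusted p with an estimated correlation). Besides Afp, the imprinted noncoding RNA gene Meg3 (in an entry shared with 2 microRNA genes) rose from 4.19 ± 1.52 to 28.8 ± 5.48 (2.55 ± 0.25), and Golm1 (1.38) and Robo1 (0.82) rose.

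Another 3 lists passed. Of 25 writers, erasers and readers of H3K36 methylation 4 fell and 1 rose (6 and 1 adjusted over the list alone; median -0.23, camera adjusted p = 0.0123, 0.675 as adjusted p with an estimated correlation), and Whsc1l1 (-0.88 ± 0.12), Ash1l (-0.60) and Setd5 (-0.54) fell beside Setd2. Setd2, the targeted gene, is itself among the 4 falls, and the list was not tested without it. Genes of oxidative phosphorylation had a median of 0.28, with 5 of 32 rising and 1 falling (13 and 1 adjusted over the list alone; camera adjusted p = 0.00037, 0.675 as adjusted p with an estimated correlation). Ndufb3 rose from 112 ± 3.12 to 184 ± 20.7 (0.71), whereas Sdha fell (-0.53). Hepatic stellate cell markers had a median of 0.55 (camera adjusted p = 0.0202, 0.847 as adjusted p with an estimated correlation), with Colec11 alone rising among 11 members (0.86, 0 members adjusted over the list alone), and KO liver 1 (0.15) lay below WT liver 2 (0.25) in the mean of the list.

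In fat metabolism single genes moved without a call for their lists. Ppara, the receptor that drives fatty acid oxidation, fell from 47.8 ± 6.37 to 16.9 ± 3.47 (-1.46 ± 0.17), and Cpt1a, which admits fatty acids to mitochondria, from 148 ± 2.53 to 69.9 ± 32.2 (-1.16 ± 0.29). Cidea, a lipid droplet protein gene, rose from 0.64 ± 0.12 to 7.29 ± 3.03 (2.26 ± 0.29), and Agpat2, of triglyceride synthesis, rose by 1.33 ± 0.28. Fasn, at 58.3 ± 15.3 and 305 ± 369, and Srebf1, at 16.1 ± 4.77 and 59.2 ± 50.8, varied widely between KO livers and did not pass (adjusted p = 0.212 and 0.0995). Medians of the lists were 0.50 for fatty acid and triglyceride synthesis (camera adjusted p = 0.286), -0.08 for lipid uptake and droplets (0.802), -0.02 for lipoproteins (0.373) and -0.11 for fatty acid oxidation and ketogenesis (0.112), where 3 of 26 members fell and all KO livers lay below all WT livers in the mean of the list. The last list passed without a filter on low FPKM (0.0452), with quantile normalization (0.0417) and without KO liver 1 (0.0251). Fatty acid and triglyceride synthesis passed without KO liver 2 (median 0.925, camera adjusted p = 0.00272). Its mean log2(FPKM + 1) minus that of WT liver was 0.51, -0.48 and 1.19 in KO livers 1, 2 and 3.

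Targets of p53 went both ways in KO normal liver, with 7 of 19 rising, 3 falling and a list median of 0.28 that did not pass (camera adjusted p = 0.147). All KO livers lay above all WT livers in the mean of this list, and it passed upward with fry (adjusted p = 0.0428). Phlda3 rose from 0.61 ± 0.15 to 3.93 ± 0.38 (1.62 ± 0.13), and the cell death genes Bax, from 20.1 ± 2.46 to 35.9 ± 3.25, and Bbc3, from 1.19 ± 0.66 to 7.50 ± 3.92, rose too. Cdkn1a, the cell cycle inhibitor gene, was 9.58 ± 4.02 and 19.6 ± 8.37 (adjusted p = 0.106). The 23 lists without a call had a camera adjusted p of 0.0643 to 0.963, among them cell cycle (median 0.00), endothelial markers (0.03), T and NK cell markers (0.10), erythroid genes (0.51) and periportal genes (0.06). For 4 of them (lipid uptake, bile acid, male-biased and periportal genes) the median, the mean and the test differed in sign. Pericentral targets had no call either, but all KO livers lay below all WT livers in their mean. They passed downward with fry (adjusted p = 0.0428). Camera called them without a filter (adjusted p = 0.0424), with a filter of mean FPKM 5 (0.0291) and without KO liver 2 (0.0181).

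In all, 2113 genes were called between KO and WT normal liver, 1089 up and 1024 down, and 471 of them changed at least 2-fold. With WT liver 3 left out the count was 240, with WT liver 2 621, with KO liver 3 654, with KO liver 2 781, and with WT liver 1 1174, and without a filter on low FPKM it was 868. Of the 16 genes with the largest changes 9 were called in each of the 6 runs that left out a library (Serinc1#2, Adgrv1, Prss8, Afp, G6pdx, Mup9, Tnfrsf12a, Mup5 and Ppl). The stellate list lost its call without KO liver 2 (camera adjusted p = 0.0778) or WT liver 3 (0.0579), with all 12 libraries in 1 fit (0.0787) and with a filter of mean FPKM 5 (0.126). Oncofetal markers lost theirs in the fit of all 12 libraries (0.0861) and the H3K36 methylation list with the filter of mean FPKM 5 (0.129).

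The genotype effect in normal liver also followed gene length. Across 10373 genes placed on the assembly, the log2 fold change fell with transcript length (Spearman's rho -0.346) and with the span of the gene (-0.276). These are relations across genes, which are not independent replicates. Among 5 groups of genes ordered by span, the shortest had a median of 0.23 and the longest a median of -0.10. In tumors the rho with span was -0.02. On these 10373 genes 1980 were called, and 1434 when each of the 12 libraries' trends with transcript length was removed, of which 1184 were among the 1980 with the same sign. With the trends removed the calls of the oxidative phosphorylation list (median 0.00, camera adjusted p = 0.897) and of the H3K36 methylation list (-0.05, 0.284) ended. The oncofetal median went from 0.40 on these genes to 0.23 (camera adjusted p = 0.0479). Calls were gained by lipoproteins, whose median went from -0.02 to -0.30 (camera adjusted p = 0.0198), and by cholangiocyte markers (0.44 to 0.52, 0.0479), while fatty acid oxidation stayed short of one (-0.12, 0.0541).

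**Figure D2:**
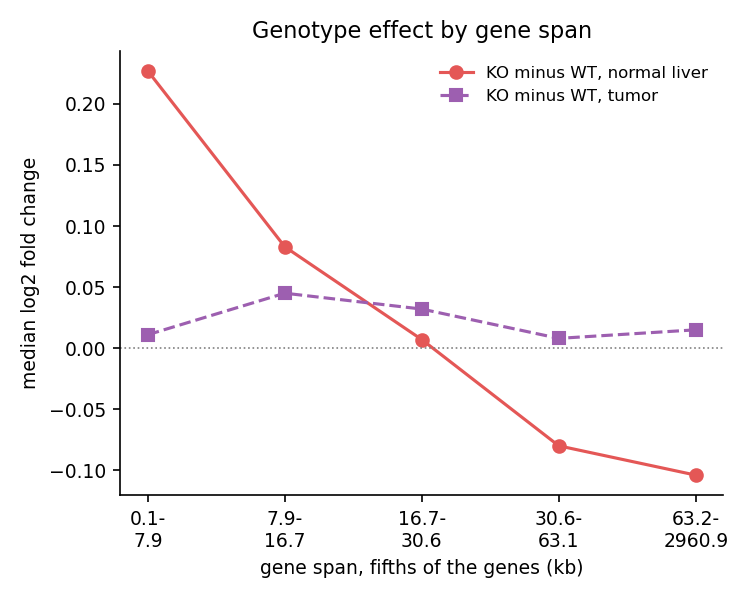
Median log2 fold change (vertical axis) of KO against WT for 5 groups of 10373 genes ordered by gene span in kb (horizontal axis), with circles for normal liver and squares for tumor. In normal liver the medians go from 0.23 in the shortest group to -0.10 in the longest, while in tumor they stay between 0.01 and 0.05.

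**Figure D3:**
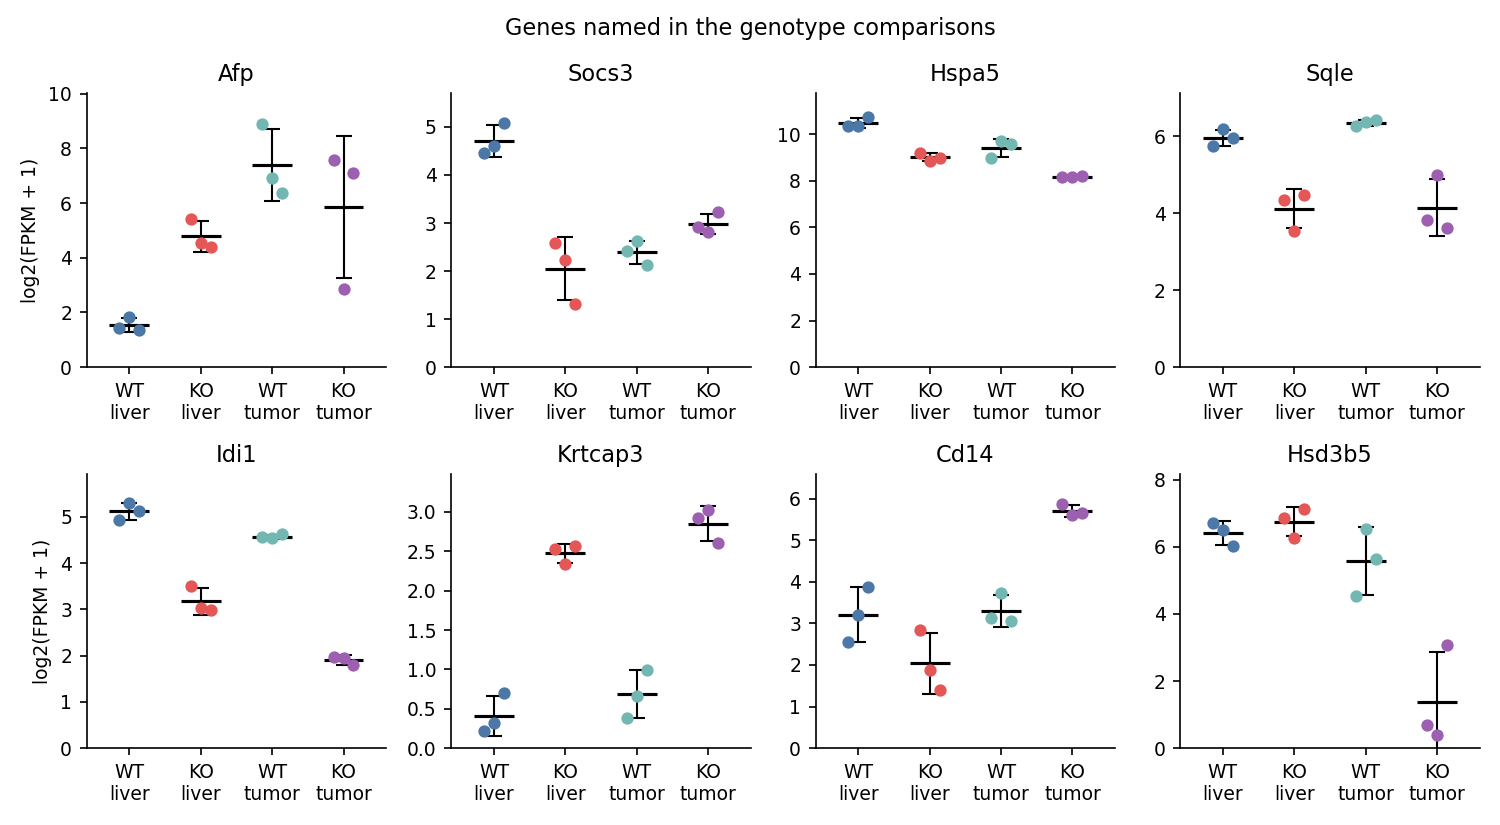
Expression as log2(FPKM + 1) (vertical axes) of 8 genes named in the genotype comparisons, in each library by group. Points are libraries, bars are means and error bars are SD (n = 3). Idi1 is lower and Krtcap3 higher in KO in both tissues, whereas Cd14 is highest in KO tumors.

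KO tumors were compared with WT tumors to see what differs with the KO genotype in DEN-induced tumors, where the lower Setd2 value had not passed its test. Cholesterol synthesis genes ranked lower in KO tumors. Idi1 fell from 22.8 ± 0.71 to 2.75 ± 0.26 (-2.67 ± 0.14, adjusted p = 0.00402), Lss, the lanosterol synthase, from 33.2 ± 6.69 to 5.12 ± 1.39 (-2.49 ± 0.23), and Cyp51, which demethylates lanosterol, from 80 ± 3.72 to 17.3 ± 4.22 (-2.17 ± 0.22). Slc22a28, of the organic anion transporter family, fell from 30.2 ± 1.16 to 5.71 ± 1.75 (-2.24 ± 0.21). Cd14, the co-receptor for bacterial lipopolysaccharide, rose from 9.09 ± 2.79 to 51.3 ± 5.15 (2.40 ± 0.23), and Ier3, an immediate early gene, from 2.99 ± 0.37 to 26.2 ± 7.83 (2.74 ± 0.23). Abcc12, an ATP-binding cassette transporter gene, rose from 0.55 ± 0.26 to 10.1 ± 3.42 (2.81 ± 0.27) and Krtcap3 from 0.63 ± 0.35 to 6.28 ± 1.07 (2.17 ± 0.21).

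Together with Mst1r, the receptor gene of macrophage-stimulating protein (mean 4.10 in WT and 0.19 in KO tumors), these were all 9 genes called, 4 up and 5 down. Mst1r lay below the expression minimum for named genes and was chosen after its values were seen. Except for Idi1, all 9 had an adjusted p of 0.0306. An unadjusted p below 0.05 was reached by 2058 genes, the 9 included, and simulated changes of 2-fold were recovered in 24% of cases.

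All 23 cholesterol synthesis genes fell when adjusted over the list alone, and 3 when adjusted over all genes. The list's median was -1.82 (camera adjusted p = 6.81e-26, adjusted p = 0.13 with an estimated correlation). Sqle was 80.5 ± 4.78 in WT and 18.4 ± 10.8 in KO tumors (-2.20 ± 0.36, adjusted p = 0.0679). Fatty acid and triglyceride synthesis genes also ranked lower, with a median of -0.75 (camera adjusted p = 3.78e-05, 0.482 as adjusted p with an estimated correlation). Of 24 members 0 were called over all genes and 7 fell adjusted over the list alone. Fads1, a desaturase gene, was 310 ± 90.0 in WT and 72.6 ± 44.8 in KO tumors (-2.23 ± 0.48, adjusted p = 0.0997).

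Interferon response genes ranked higher in KO tumors, the list call that held with an estimated correlation (median 1.13, camera adjusted p = 4.25e-13, adjusted p = 0.0327 with an estimated correlation). Of 29 members 0 were called over all genes and 20 rose adjusted over the list alone. The antiviral genes Oas1a and Oas1g, which share an entry, were at 3.16 ± 1.41 in WT and 19.5 ± 1.07 in KO tumors (2.36 ± 0.28, adjusted p = 0.0512), and Irf7, a regulator of interferon genes, at 23.5 ± 1.89 and 93.7 ± 33.4 (1.90 ± 0.27, 0.0544). Oasl2 stood at 1.69 ± 0.23 and Oasl1 at 1.62 ± 0.25.

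Genes of the extracellular matrix and of immune cells ranked higher too. For the matrix the median was 1.43 (camera adjusted p = 1.2e-13, 0.406 as adjusted p with an estimated correlation), with 0 of 27 members called over all genes and 21 rising adjusted over the list alone. Col5a2 stood at 1.53 ± 0.19, Lum at 1.38 ± 0.21, and Col1a1, a fibrillar collagen chain, at 2.60 ± 0.47 (4.26 ± 0.69 in WT and 35.8 ± 23.1 in KO tumors, adjusted p = 0.0775). Macrophage and Kupffer cell markers had a median of 1.12 (10 of 19 adjusted over the list alone), antigen presentation class II genes 1.61 (6 of 7) and neutrophil markers 1.30 (5 of 5), again with 0 called over all genes. Their camera adjusted p were 7.03e-06, 0.000561 and 6.46e-05, and their adjusted p with an estimated correlation 0.242, 0.482 and 0.13. Trem2, a receptor of lipid-associated macrophages, was 1.48 ± 0.30 in WT and 7.11 ± 3.22 in KO tumors (adjusted p = 0.0734). Endothelial markers (median 0.30, camera adjusted p = 0.118), T and NK cell markers (0.22, 0.936, with a mean of 0.13 and a test direction of down) and erythroid genes (1.11, 0.157) did not pass. Cell cycle genes had a median of 0.35 (0.0502). They passed in several other settings, such as median-of-ratios scaling (camera adjusted p = 0.0267) and array quality weights (0.00538). Without KO tumor 3 their median was 0.69 (4.52e-07). Endothelial markers passed without WT tumor 1 (median 0.45, camera adjusted p = 0.00984) and with array quality weights (0.0222).

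Targets of glutathione metabolism and NRF2, the regulator of antioxidant genes, had a median of 1.36 (camera adjusted p = 7.53e-09, 0.156 as adjusted p with an estimated correlation). Of 21 members 0 were called over all genes and 14 rose adjusted over the list alone, and Nqo1 was 11.2 ± 2.44 in WT and 65.2 ± 23.1 in KO tumors (2.39 ± 0.32, adjusted p = 0.0512). Medians were 0.86 for the acute phase response (3 of 22 rising adjusted over the list alone, camera adjusted p = 0.000434) and 0.67 for AP-1 and immediate early genes, with Ier3 called (0.00382). They were 0.56 for stellate cell markers (2 of 11, 0.0326) and 0.67 for cholangiocyte markers (0 of 10, 0.0489). All 4 had an adjusted p of 0.482 with an estimated correlation.

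Several programs of the hepatocyte ranked lower in KO tumors, with 0 members called over all genes. Male-biased liver genes had a median of -1.68 (camera adjusted p = 3.44e-05, 5 of 24 falling adjusted over the list alone), and Hsd3b5, a male-specific steroid enzyme gene, was 54.3 ± 35.6 in WT and 2.78 ± 4.01 in KO tumors (-4.18 ± 0.79, adjusted p = 0.0828). Pericentral beta-catenin targets had a median of -0.83 (4.85e-05, 0 of 17), the unfolded protein response -0.54 (3.5e-05, 7 of 24), hepatocyte identity -0.29 (0.0072, 4 of 27), and urea cycle and amino acid catabolism -0.43 (0.0121, 0 of 25). Adjusted p with an estimated correlation was 0.482 for the first 4 of these lists and 0.674 for the last.

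With improbable zeros left in, the separation of KO from WT tumors was incomplete for these 5 lists and for fatty acid and triglyceride synthesis. Mean log2(FPKM + 1) of the pericentral members minus that of WT liver was -2.23, -2.59 and -0.69 in KO tumors 1, 2 and 3, against -1.12, -0.59 and -0.98 in WT tumors. For male-biased liver genes it was -3.36, -2.90 and -0.79 against -1.78, -0.06 and -0.26, and for urea cycle and amino acid catabolism -1.32, -1.50 and -0.20 against -0.92, -0.63 and -0.45. KO tumors 1 and 2 thus carried these falls, and KO tumor 3 lay among or above the WT tumors. For hepatocyte identity the values were -1.15, -1.28 and -0.53 against -2.04, -0.40 and -0.36. WT tumor 1 was lowest, with zeros for Serpina1b, Ahsg and Trf counted. With improbable zeros treated as missing, a choice made after the data were seen, this list kept 24 members and a median of -0.41 (camera adjusted p = 0.00121). For the unfolded protein response the values were -0.99, -0.77 and -0.85 against -0.85, -0.17 and -0.43. The value of WT tumor 1 counts a zero of Dnajb11, and separation was not examined without it. With such zeros missing, this list kept 23 members and a median of -0.60 (camera adjusted p = 1.44e-05). For fatty acid and triglyceride synthesis KO tumor 1 (-1.43) stood apart from KO tumors 2 and 3 (-0.31 and -0.32) and from WT tumors (-0.37, 0.34 and 0.37).

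The count of 9 depended on single libraries. It was 266 without KO tumor 3, 0 without WT tumor 1 or WT tumor 2, 2 without KO tumor 1 or WT tumor 3, and 3 without KO tumor 2, and it was 1017 when all 12 libraries shared 1 fit and 235 with array quality weights. None of the 8 genes named by the rule was called in each of the 6 runs, with Idi1 called in 4 of them. The AP-1 list lost its call without KO tumor 3 (camera adjusted p = 0.121) and hepatocyte identity without KO tumor 2 (0.131) and with quantile normalization (0.0674). Medians moved with single libraries for hepatocyte identity, from -0.12 without KO tumor 2 to -0.73 without WT tumor 1, and for urea cycle genes, from -0.14 without KO tumor 2 to -0.78 without KO tumor 3. Pericentral targets went from -0.45 without KO tumor 2 to -1.28 without KO tumor 3, fatty acid and triglyceride synthesis was at -0.31 without KO tumor 1, and without KO tumor 3 AP-1 genes were at 0.42 and stellate markers at 0.24. The urea cycle list lost its call without KO tumor 1 (0.14), KO tumor 2 (0.345) or WT tumor 3 (0.068), the stellate list without KO tumor 3 (0.419) or WT tumor 2 (0.055) and without a filter (0.0718), and the cholangiocyte list without KO tumor 1 (0.0789), KO tumor 2 (0.154), WT tumor 1 (0.0851) or WT tumor 3 (0.0806), without a filter (0.0756), with a pseudocount of 5 (0.054), with array quality weights (0.116) and in the fit of all 12 libraries (0.0593).

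The KO effects of both tissues overlapped in 3 of the 9 tumor calls, where 0.37 shared rises and 0.44 shared falls were expected by chance. Idi1 and Cyp51 fell and Krtcap3 rose in both. Krtcap3 rose by 2.06 ± 0.16 in normal liver, from a mean of 0.34 to 4.57, and Cyp51 fell by 1.16 ± 0.17. Of the genes called in normal liver 64.6% had the same sign in tumor, and Pearson's r between both KO effects was 0.16 across 11671 genes. Without KO tumor 3 the overlap was 35, without WT tumor 1 or WT tumor 2 it was 0, and without KO tumor 1 or WT tumor 3 it was 1. Idi1 lies on chromosome 13 (8885501 to 8892451), Cyp51 on chromosome 5 (4081145 to 4104746) and Krtcap3 on chromosome 5 (31251691 to 31253202), all apart from Setd2.

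The test of the difference asks for which genes KO and WT differed otherwise in tumor than in normal liver. All tumors came from mice given DEN and no normal liver did, so tumor and carcinogen cannot be told apart here. The lower Setd2 value of KO tumors had not passed its own test. It called 243 genes, 134 with a more positive effect in tumor and 109 with a more negative one. Cd14 (3.57 ± 0.54) and Ier3 (3.37 ± 0.30) had risen in KO tumors. Tnfrsf12a fell in KO liver but was 71.7 ± 12.4 in WT and 99.4 ± 41.9 in KO tumors (difference 3.63 ± 0.54). Cybb, a subunit of the phagocyte oxidase, was 3.13 ± 0.52 and 2.92 ± 0.26 in WT and KO liver and 4.80 ± 2.31 and 63.6 ± 34.1 in WT and KO tumors (3.42 ± 0.58). Mt2, a metallothionein, differed most (7.89 ± 1.80, adjusted p = 0.0499), followed among the positive genes by Srxn1 (3.72 ± 0.73), an antioxidant enzyme gene.

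More negative effects in tumor were found for Hsd3b5 (-4.52 ± 0.92), Serpina12 (-3.72 ± 0.63), which encodes the adipokine vaspin, and Sucnr1 (-3.52 ± 0.77), the succinate receptor gene. Serpina12 was 67.8 ± 20.2 and 151 ± 25.1 in WT and KO liver but 349 ± 69.0 and 72.2 ± 60.6 in WT and KO tumors. Sucnr1 was 13.8 ± 3.36 and 82.5 ± 18.6 in WT and KO liver and 19.9 ± 6.47 and 12 ± 9.57 in WT and KO tumors. The entry of Xlr3a and Xlr3c (-3.36 ± 0.76) and Wfdc15b (-3.26 ± 0.73) completed the named genes.

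Of the lists, 8 had a more positive and 5 a more negative KO effect in tumor. Cholesterol synthesis was more negative (median difference -1.23, camera adjusted p = 9.85e-10, 0.316 as adjusted p with an estimated correlation), with 4 of 23 members called and 16 adjusted over the list alone, among them Insig1 (-2.94) and Lss (-2.25). AP-1 and immediate early genes (1.69), the acute phase response (1.51), neutrophil markers (1.39), extracellular matrix (1.34), macrophage markers (1.31), class II genes (1.13), NRF2 targets (1.04) and the interferon response (0.73) were more positive. In this order 3, 3, 1, 4, 0, 0, 5 and 4 members were called over all genes, and 5, 10, 2, 20, 9, 0, 10 and 11 adjusted over the list alone. Socs3 (3.26), Klf6 (2.69), Col4a1 (2.73), Il1b (2.13) and Gsta1 (2.42) were among the called members. Male-biased genes (-1.53), fatty acid and triglyceride synthesis (-1.32), pericentral targets (-0.71) and oxidative phosphorylation (-0.37) were more negative, with Hsd3b5 the only member called over all genes and 3, 0, 1 and 0 members adjusted over the list alone. Adjusted p with an estimated correlation was 0.316 to 0.948 over the 13 lists.

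Without KO tumor 3 the count of the difference was 1368, without WT liver 2 it was 7, without KO liver 3 9, without WT liver 3 10, without WT tumor 3 18, without KO liver 2 22, without WT tumor 2 29, without KO tumor 1 96, without KO tumor 2 146, and without WT tumor 1 370. None of the 10 named genes was called in each of the 12 runs, and 2 lists lost their calls in some of them or in other settings. They were pericentral targets, without KO liver 2 (camera adjusted p = 0.0656), KO tumor 1 (0.149), KO tumor 2 (0.385) or WT tumor 2 (0.117) and with a filter of mean FPKM 5 (0.21), and class II genes, without KO liver 1 (0.0522), KO tumor 1 (0.134), KO tumor 2 (0.134), WT liver 2 (0.0964) or WT tumor 2 (0.091), without a filter (0.0586), rescaled to a common sum (0.0589) and with entries of 1 gene name (0.0567). Medians moved with KO tumors too, for male-biased genes to -0.93 without KO tumor 1 and -2.30 without KO tumor 3, for oxidative phosphorylation to -0.20 and -0.59 without the same libraries, and for pericentral targets to -0.20 without KO tumor 2 and -1.31 without KO tumor 3. The class II median was 0.62 without KO tumor 2. The 19 lists without a call had a camera adjusted p of 0.122 to 0.973, and the p53 and stellate lists differed in sign between median, mean and test. Without KO tumor 3, calls were gained by cell cycle genes (median 0.782, camera adjusted p = 1.35e-05) and drug-metabolising cytochrome P450 genes (-1.069, 0.000261). Urea cycle genes (-0.667, 0.000407) and bile acid genes (-1.041, 0.000943) gained theirs in the same run.

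**Figure D4:**
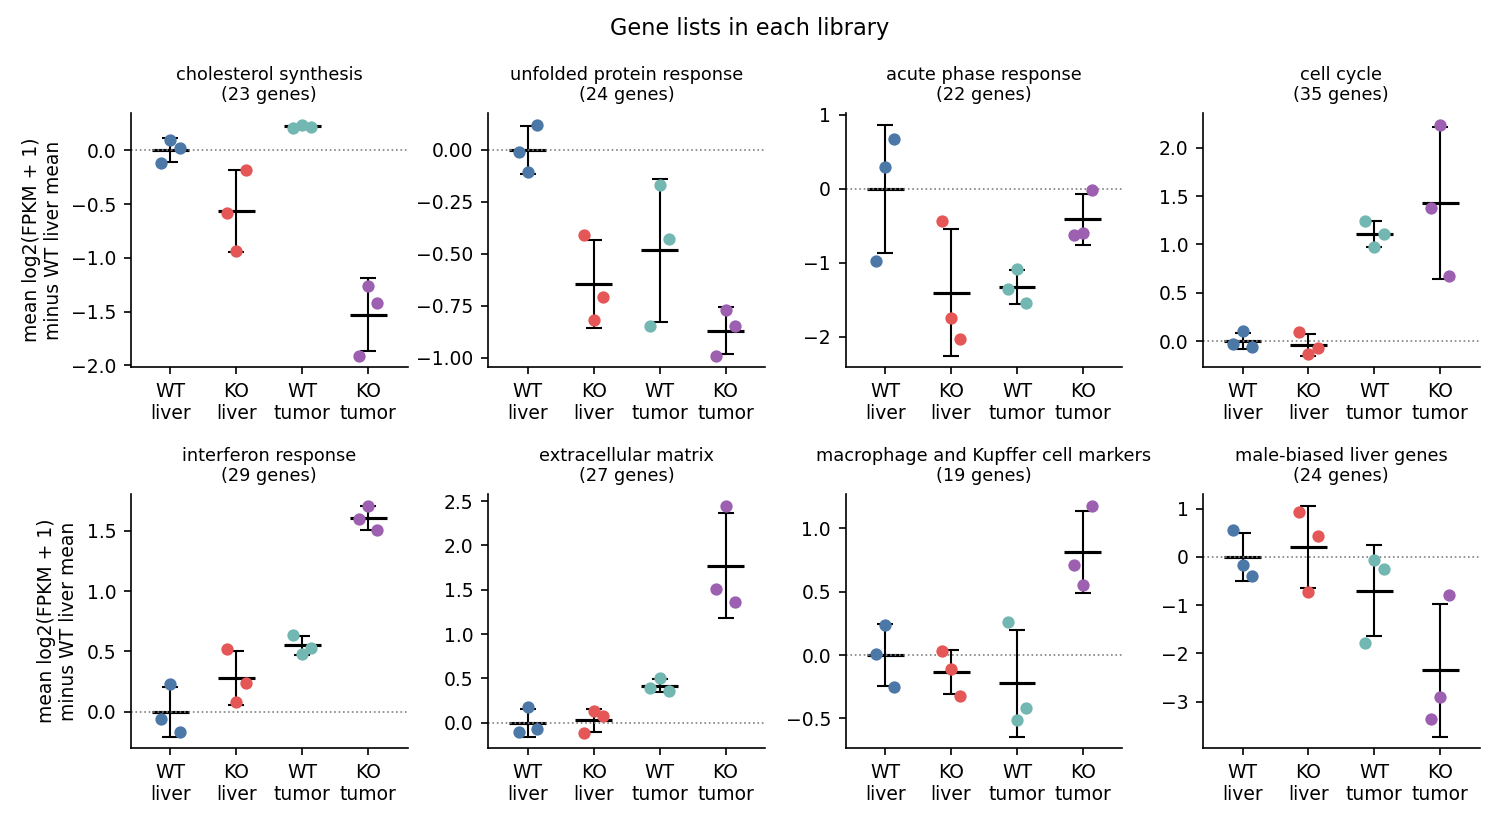
Mean log2(FPKM + 1) of the members of 8 gene lists minus their mean in WT liver (vertical axes), in each library by group. Points are libraries, bars are means and error bars are SD (n = 3). Cholesterol synthesis lies between -1.91 and -1.26 in KO tumors and between 0.21 and 0.24 in WT tumors.

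Tumors were also compared with normal liver within each genotype. Only the tumors came from mice given DEN, so changes called tumor changes below may belong to the tumor or to the carcinogen. In WT, Tff3, a secreted trefoil peptide gene, rose from 2.82 ± 1.09 to 789 ± 397 (7.57 ± 0.42), and Cyp2a4, a female-biased steroid hydroxylase gene, from 11.4 ± 2.31 to 1885 ± 2106 (6.66 ± 0.69). Afp rose from 1.95 ± 0.56 to 224 ± 215 (5.85 ± 0.59) and Spink1, a trypsin inhibitor gene, from 0.87 ± 0.53 to 112 ± 57.3 (5.82 ± 0.39). Akr1c18 (6.13), Wfdc15b (5.39), Bex1 (4.63) and Cd63 (4.53) also rose. The metallothioneins Mt2 (4981 ± 3181 to 212 ± 127, -4.39 ± 0.69) and Mt1 (-3.48) fell, as did the lysophospholipid transporter gene Mfsd2a (-3.14), Gadd45g (-3.05) and the entries of Mup9 (-4.74), Mup5 (-3.93), Mup1 (-3.54) and Mup6 (-2.83).

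Cell cycle genes rose in WT tumors, with 28 of 35 called (29 adjusted over the list alone), a median of 1.11 and a camera adjusted p of 2.53e-19. Cdk1, the mitotic kinase, rose from 0.30 ± 0.01 to 3.50 ± 0.14 (1.79) and Mki67 from 0.25 ± 0.15 to 1.90 ± 0.50 (1.20). Of 23 oncofetal and liver cancer markers 13 rose and 0 fell, also adjusted over the list alone (median 2.12, camera adjusted p = 2.86e-09). Fatty acid oxidation and ketogenesis fell, with 20 of 26 called down and 1 up (23 and 1 adjusted over the list alone; median -0.81, camera adjusted p = 2.46e-08), and Ppara fell by 1.21 ± 0.16. Drug-metabolising cytochrome P450 genes (-1.14, 15 of 27 down and 2 up), bile acid synthesis and transport (-0.86, 8 of 22 down), pericentral targets (-0.94, 10 of 17) and urea cycle and amino acid catabolism (-0.64, 12 of 25) ranked lower. The same held for hepatocyte identity (-0.68, 7 of 27), male-biased genes (-1.11, 8 of 24), oxidative phosphorylation (-0.40, 8 of 32), the acute phase response (-1.03, 7 of 22 down and 1 up) and the unfolded protein response (-0.54, 5 of 24 down and 2 up). Adjusted over the list alone, 18, 12, 11, 15, 9, 12, 16, 14 and 11 members of these 9 lists fell. Glul, the pericentral glutamine synthetase gene, fell from 357 ± 7.19 to 156 ± 44.5 (-1.22). WT tumor 1 had the lowest values in 2 of these lists. Its mean log2(FPKM + 1) minus that of WT liver was -2.04 for hepatocyte identity and -1.78 for male-biased liver genes. WT tumors 2 and 3 had -0.40 and -0.36 for the first list and -0.06 and -0.26 for the second. The values of WT tumor 1 count its improbable zeros, of Serpina1b, Ahsg and Trf in the first list and of Serpina1e in the second. How far it stands apart without these zeros was not examined. Without WT tumor 1 the medians were -0.46 (camera adjusted p = 0.0272) and -0.62 (0.00959). With improbable zeros treated as missing, hepatocyte identity had -0.65 over 24 members (0.000377) and male-biased genes -1.11 over 21 (3.45e-05).

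Class II genes (1.48, 5 of 7), cholangiocyte markers (0.82, 4 of 10), interferon response genes (0.50, 5 of 29) and matrix genes (0.32, 8 of 27) ranked higher in WT tumors, and 6, 5, 10 and 9 members rose adjusted over the list alone. H2-Ab1 rose from 20.1 ± 8.36 to 63.6 ± 7.91 and Sox9, a duct and progenitor factor gene, from 0.84 ± 0.15 to 3.64 ± 1.67. Among the 16 lists without a call (camera adjusted p = 0.052 to 0.807) were p53 targets (0.23), T and NK cell markers (0.65) and cholesterol synthesis (0.36), where Lss rose by 1.38. Cholesterol synthesis passed upward with quantile normalization (camera adjusted p = 0.000744), a filter of mean FPKM 5 (0.00672), without WT liver 2 (0.033) and rescaled to a common sum (0.0489). All WT tumors lay above all WT livers in the mean of this list. In some settings p53 targets and T and NK cell markers passed too. Median, mean and test differed in sign for 4 of the 16 lists (NRF2, stellate, macrophage and endothelial). Camera adjusted p of the 16 lists called lay at 0.00994 or below, and none held with an estimated correlation (adjusted p = 0.285 to 0.489). In all 1981 genes were called, 935 up and 1046 down, of which 10 of the 16 named genes were called in each of 6 runs. The count was 454 without WT liver 3, 912 without WT liver 2, 1091 without WT tumor 2, 1104 without WT liver 1 and 1274 without WT tumor 3. Quantile normalization ended the calls of hepatocyte identity (camera adjusted p = 0.0964), the unfolded protein response (0.179, and 0.0526 with a filter of mean FPKM 5), oxidative phosphorylation (0.641) and cholangiocyte markers (0.0754), the last also without a filter (0.0548) and rescaled to a common sum (0.0692). Rescaling each library to a common sum moved the median of all genes by 0.27 and the share of calls going up from 47.2% to 80.3%, so directions here are relative to the deposited scale.

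In KO, tumors differed from normal liver in Ubd, a ubiquitin-like modifier gene, which rose from 1.56 ± 0.34 to 132 ± 84.5 (5.40 ± 0.57), and Lcn2, an iron-binding acute phase protein gene, from 70.8 ± 56.0 to 2525 ± 1231 (5.34 ± 0.65). Spink1 (5.32), Cyp2a4 (5.23), D17H6S56E-5 (5.13), Akr1c18 (4.94), Ly6d (4.84) and the entry of the imprinted RNA gene H19 (4.99) rose. H19 was 15.9 ± 3.41 in KO liver and 2066 ± 3300 in KO tumors. The fatty acid elongase gene Elovl3 fell from 314 ± 187 to 4.40 ± 4.28 (-6.02 ± 0.71) and Hsd3b5 from 110 ± 31.6 to 2.78 ± 4.01 (-5.37 ± 0.67). Pon1, the paraoxonase gene (-4.17), the organic anion transporter gene Slco1a1 (-4.10), and the entries of Mup1 (-7.28), Mup8 (-6.06), Mup16 (-4.90) and 4 joined Mup genes (-5.74) fell.

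Matrix genes rose in KO tumors against KO liver, with 16 of 27 called (23 adjusted over the list alone; median 1.63, camera adjusted p = 1.26e-11), and Col1a1 rose from 1.29 ± 0.19 to 35.8 ± 23.1 (3.79 ± 0.46). Interferon response genes rose (17 of 29, 24 adjusted over the list alone; median 1.21, 1.26e-11), with Isg15 going from 13.2 ± 3.20 to 60.6 ± 2.96 (2.14). Cell cycle (1.54, 14 of 35), oncofetal markers (1.83, 11 of 23), macrophage markers (1.40, 9 of 19), class II genes (2.60, 6 of 7), AP-1 genes (1.21, 7 of 18) and NRF2 targets (0.68, 7 of 21) ranked higher. Cholangiocyte markers (0.82, 4 of 10), female-biased genes (1.0, 5 of 15 up and 1 down) and the acute phase response (0.65, 2 of 22) ranked higher too. Adjusted over the list alone, 29, 15, 12, 6, 10, 8, 4, 6 and 2 members of these 9 lists rose.

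Male-biased genes had the lowest median in KO tumors against KO liver (-2.48, 11 of 24 falling), followed by pericentral targets (-1.44, 6 of 17), drug-metabolising cytochrome P450 genes (-1.21, 3 of 27 down and 2 up), cholesterol synthesis (-1.13, 9 of 23) and bile acid genes (-1.10, 5 of 22 down and 1 up). Fatty acid and triglyceride synthesis (-1.06, 1 of 24), oxidative phosphorylation (-0.85, 5 of 32), urea cycle and amino acid catabolism (-0.85, 2 of 25), fatty acid oxidation (-0.56, 1 of 26), hepatocyte identity (-0.48, 1 of 27) and the unfolded protein response (-0.36, 5 of 24 down and 1 up) passed as well. Adjusted over the list alone, 14, 11, 11, 13, 12, 1, 26, 2, 0, 0 and 7 members of these 11 lists fell. With rescaling to a common sum the unfolded protein response turned to a median of 0.07. KO tumors were not separated from KO livers for cytochrome P450, fatty acid oxidation, fatty acid and triglyceride synthesis, hepatocyte identity, the unfolded protein response or, among the lists that ranked higher, the acute phase response. For drug-metabolising cytochrome P450 the mean log2(FPKM + 1) minus that of WT liver was -1.44, -1.84 and 0.25 in KO tumors 1, 2 and 3, against 0.18, 0.18 and 0.03 in KO livers, so that KO tumors 1 and 2 carried the fall.

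Of the 22 lists called in KO, with a camera adjusted p of 0.0253 or below, none held with an estimated correlation (adjusted p = 0.247 to 0.551). The 10 others had a camera adjusted p of 0.0609 to 0.767, with signs that differed for stellate and erythroid genes. The comparison called 1664 genes, 1061 up and 603 down, and 6 of the 16 named genes were called in each of 6 runs (Ubd, Lcn2, Spink1, Cyp2a4, D17H6S56E-5 and Elovl3). The count was 2981 without KO tumor 3, 129 without KO liver 3, 138 without KO liver 2, 307 without KO liver 1, 530 without KO tumor 1 and 1045 without KO tumor 2, and 543 without a filter. Quantile normalization ended the calls of fatty acid oxidation (camera adjusted p = 0.0734), hepatocyte identity (0.742) and the unfolded protein response (0.762, and 0.107 without KO liver 1). With a filter of mean FPKM 5 hepatocyte identity (0.0969), the unfolded protein response (0.11) and drug-metabolising cytochrome P450 genes (0.0625) lost theirs. Female-biased genes lost theirs without KO tumor 3 (0.324), without a filter (0.075), rescaled to a common sum (0.218) and in the fit of all 12 libraries (0.157), the acute phase response without KO liver 3 (0.102), KO tumor 3 (0.181) or a filter (0.0654) and with array quality weights (0.0654), and cholangiocyte markers without KO liver 1 (0.0565) and rescaled (0.0777). Medians that moved were those of P450 genes (-0.78 without KO tumor 1), bile acid genes (-0.70 without KO tumor 1 and -1.66 without KO tumor 3), fatty acid oxidation (-0.88 without KO tumor 3), NRF2 targets (0.45), cholangiocyte markers (0.38) and urea cycle genes (-0.55, all 3 without KO tumor 2). The same held for fatty acid and triglyceride synthesis (-0.54) and the acute phase response (0.39) without KO liver 3, and for the unfolded protein response (-0.23) without KO liver 1. Rescaling to a common sum moved the median of all genes by 0.38 and the share going up from 63.8% to 86.4%.

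Tumor changes were shared between genotypes in 492 genes called in both with the same sign, 340 up and 152 down, where 85.0 and 54.0 were expected by chance. Opposite signs were found for 13, and r between both tumor effects was 0.53 across 11671 genes. Spink1, Cyp2a4, Akr1c18 and Mup1 were among the named genes of both genotypes. The shared count was 832 without KO tumor 3 and 58 without KO liver 2, and it was 61 without KO liver 3, 91 without KO liver 1, 147 without WT liver 3, 163 without KO tumor 1, 251 without WT liver 1, 275 without WT liver 2, 316 without WT tumor 2 and 323 without KO tumor 2.

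**Figure D5:**
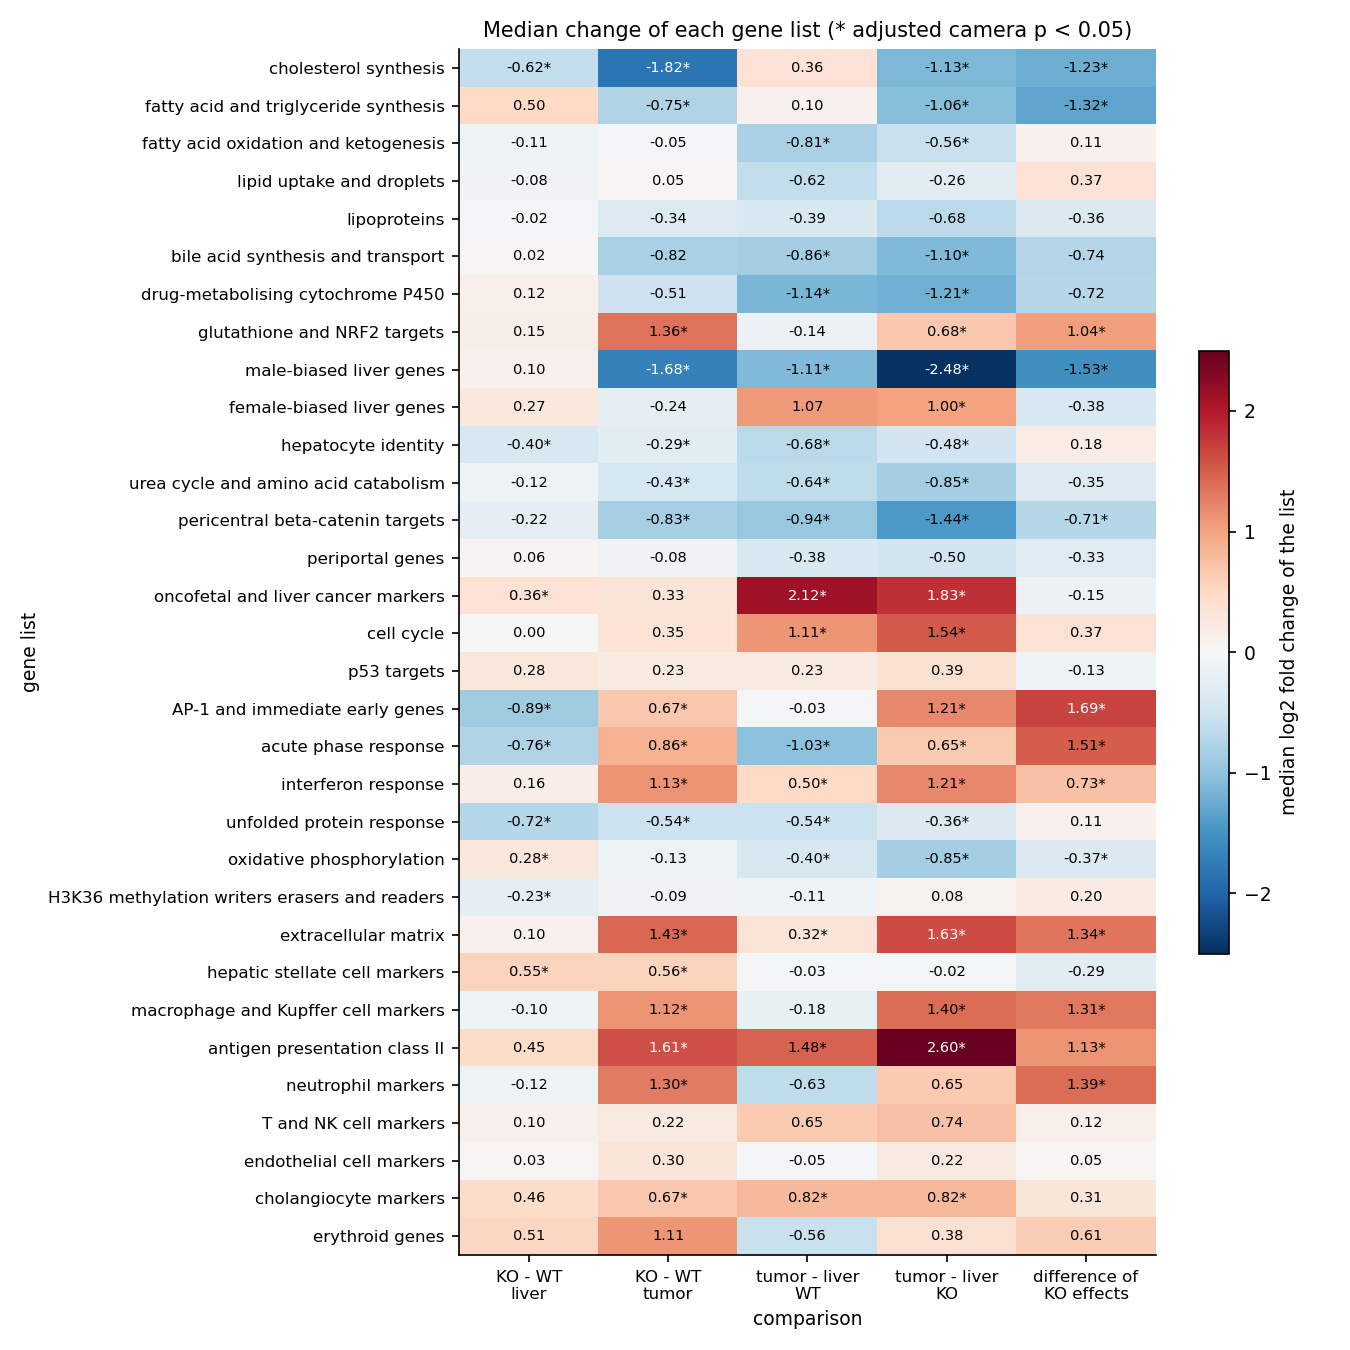
Median log2 fold change of the members of each of 32 gene lists (vertical axis) in the 5 comparisons (horizontal axis), printed and colored from blue for lower to red for higher. Stars mark lists with a camera adjusted p below 0.05 at the preset correlation. Cholesterol synthesis reaches -1.82 between KO and WT tumors and 0.36 between WT tumors and WT liver.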

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

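The tests of a smaller share of hepatocytes and of the scaling of the libraries were chosen after the result was seen. Differences of genes and lists come from the test of the difference between the KO effect in tumor and in normal liver (log2, tumor minus normal liver), whereas the tests of hepatocyte share and scaling compare KO with WT tumors. The genes and lists are among those for which this difference passed. Of 100 drawn splits of the 12 libraries, 2 gave as many calls as the real split with its 243, the real one included. The other was the split that set the KO livers and WT tumors against the rest, with 1677 calls, which adds up the KO effects of both tissues and points to a structure of the samples. The next splits gave 205 (KO livers, KO tumor 1 and WT tumors 1 and 3 against the rest) and 71 calls (KO livers, KO tumor 3 and WT tumors 2 and 3).

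Lower expression of cholesterol synthesis genes in KO tumors than in WT tumors was stronger than in normal liver, with a difference of -1.23 for the list, -2.94 for Insig1, -2.25 for Lss and -1.41 for Fdft1. If fewer hepatocytes in the KO tumors were the cause, the list would have fallen no more than hepatocyte identity genes. It fell further between KO and WT tumors (difference of medians -1.41, 95% interval -1.92 to -0.95, over list members rather than libraries). Hepatocyte identity stood at -0.41 over the 24 members left without 3 that had improbable zeros. Male-biased genes, however, had a similar median (-1.68) and pericentral targets a smaller fall (-0.83), neither with KO and WT tumors separated. A smaller share is thus argued against only as far as hepatocyte identity genes measure it. Under 3 other scalings the list's median between KO and WT tumors came no nearer to 0 than -1.78. These scalings moved the median of all genes by only 0.11, -0.06 and -0.05, so they could not have brought the list near 0. The test shows only that the choice among them does not make the fall. A lower activity of sterol synthesis in KO tumor cells may be the reason, a hypothesis that these data raised and that was not tested itself. The 10 splits of the 6 tumors are too few for a share under 0.1, with 9 genes called in the real split and 1 in the highest of the others.

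Matrix, interferon and macrophage genes had a more positive KO effect in tumor, with differences of 1.34, 0.73 and 1.31 for the lists. Called members were Col4a1 (2.73), Col1a1 (2.60), Thbs1 (1.92), Col5a2 (1.55), Oas1a and Oas1g (1.96), Oasl2 (1.68), Gbp3 (1.59) and Xaf1 (1.30). If a smaller share of hepatocytes raised the markers of every other cell type alike, the 3 lists would lie level with endothelial markers. The interferon list, however, holds induced genes rather than markers of a cell type, so its level does not bear on that share. The 3 lists were also picked after their rise was seen. All 3 lay above endothelial markers in KO against WT tumors, with the lowest bound for the interferon response (0.82, 95% interval 0.36 to 1.29). The difference was 1.13 (0.77 to 1.54) for the matrix and 0.81 (0.41 to 1.40) for macrophage markers. All intervals of this paragraph are over list members rather than libraries, so they leave out the spread between tumors. The lowest median of the 3 lists under other scalings was 1.06. These scalings moved the median of all genes by only 0.11, -0.06 and -0.05, so they could not have brought the lists near 0. Stellate markers (0.26 above endothelial ones, -0.76 to 1.15) and T and NK cell markers (-0.08, -0.79 to 0.47) were not shown to differ from endothelial markers. The endothelial list, as mean log2(FPKM + 1) minus that of WT liver, was -0.02, -0.1 and 0.43 in KO tumors and 0.32, -0.17 and -0.25 in WT tumors. Without WT tumor 1 it passed (median 0.45, camera adjusted p = 0.00984). Whether endothelial cells kept their share among the other cells was not tested, so a smaller share of hepatocytes stays open. More macrophages or fibroblasts in the KO tumors, or a stronger response of the same cells, may both be the reason, no test here separates them, and KO tumor libraries differed most among themselves (median SD 0.31).

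Myeloid and inflammation genes differed by 3.57 for Cd14, 3.42 for Cybb, 2.13 for Il1b, 1.39 for neutrophil markers and 1.13 for class II genes. Acute phase and metal response values were 1.51 for the list, 7.89 for Mt2, 3.26 for Socs3 and 1.65 for Lbp. AP-1 and immediate early genes differed by 1.69, with Ier3 at 3.37, Klf6 at 2.69 and Fosl2 at 1.79. Targets of NRF2 differed by 1.04, with Srxn1 at 3.72, Gsta1 at 2.42, Nqo1 at 1.83, Txnrd1 at 1.34 and Ugdh at 1.27. Other positive differences were 3.63 for Tnfrsf12a, 3.11 for Ppl and 2.71 for Abcc12. A positive difference also arises where a gene fell in KO normal liver. Socs3, Klf6, Fosl2, Srxn1, Tnfrsf12a and Ppl were called lower there, whereas Cd14, Ier3 and Abcc12 were called higher in KO tumors. The acute phase median, KO against WT, was -0.76 in normal liver and 0.86 in tumor, and that of AP-1 genes -0.89 and 0.67.

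Negative differences were -1.53 for male-biased genes, -4.52 for Hsd3b5, -1.32 for fatty acid and triglyceride synthesis, -0.71 for pericentral targets and -0.37 for oxidative phosphorylation. Single genes were Serpina12 (-3.72), Sucnr1 (-3.52), the entry of Xlr3a and Xlr3c (-3.36), Wfdc15b (-3.26), Prss8 (-2.85), Bbc3 (-2.56), Slc22a28 (-2.28), Mst1r (-2.17) and Phf1 (-1.02). Prss8 and Bbc3 had risen in KO normal liver, while Slc22a28 and Mst1r were called lower in KO tumors.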

How the results depend on the processing

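Treating improbable zeros as missing, keeping entries with 1 gene name found once, and removing the transcript length trend were chosen after the data were seen. No called gene or list reversed the direction of its test in the alternatives run for it, but rescaling to a common sum turned the median of the unfolded protein response in KO tumors against KO liver to 0.07. Counts are given in the order KO normal liver, KO tumor, tumor in WT, tumor in KO and difference of the KO effect, against 2113, 9, 1981, 1664 and 243, and the overlaps of KO calls and of tumor calls against 3 and 492. The cause was not tested, except that leaving out a library also removes replicates.

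Without a filter on low FPKM the counts were 868, 1, 1257, 543 and 56, and the overlaps 1 and 70. With a filter of mean FPKM 5 tumor in WT gave 1263, tumor in KO 670, the difference 133, and the tumor overlap 211. Rescaled to a common sum, KO tumor gave 24, the difference 115, and the KO overlap 7. With median-of-ratios scaling KO tumor gave 14 and the KO overlap 5, and with quantile normalization 16 and 6, with a tumor overlap of 304. In 1 fit of all 12 libraries the first 4 counts were 1144, 1017, 1105 and 3340, with a KO overlap of 98. Array quality weights gave 235 for KO tumor, 3024 for tumor in WT, 608 for the difference, and overlaps of 46 and 823. With entries of 1 gene name KO tumor gave 44 and the KO overlap 10, and with the length trend removed KO tumor gave 18, against 45 on the same 10373 placed genes before. The replicate number as a block gave 153, 0, 1235 for the first 3 counts, 114 for the difference, and overlaps of 0 and 327. Numbers were not seen to pair the libraries, since 3 of 18 pairs with the same number correlated above 0.1 (-0.276 to 0.347, the highest for KO tumor 1 with WT tumor 1). With 3 libraries per group these correlations cannot exclude a handling shared by number. Where an alternative or a count is not given here, it stayed within 1.5 times.

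Leaving out 1 library in turn gave 240 to 1964 for KO normal liver, 0 to 266 for KO tumor, 454 to 2134 for tumor in WT, 129 to 2981 for tumor in KO, 7 to 1368 for the difference, 0 to 35 for the KO overlap and 58 to 832 for the tumor overlap. KO tumor 3 gave the highest value in 5 of these results when left out, KO liver 1 gave the 1964 and WT tumor 1 the 2134, and the libraries behind the lowest values are named with each comparison above. Calls of named genes stayed in 4308 of the comparisons with other settings and were lost in 549, and with a library left out they stayed in 1406 and were lost in 958. Of 77 list calls 1 held with an estimated correlation, 31 with fry, 69 with quantile normalization, 71 without a filter, 73 rescaled to a common sum, 75 with the length trend removed or array quality weights, 76 with a pseudocount of 5 or entries of 1 gene name, and 77 with median-of-ratios scaling, a pseudocount of 0.1, a block, no variance trend or improbable zeros missing. With a filter of mean FPKM 5 the calls held in 65 lists and were lost in 7, and in the fit of 12 libraries in 60 and 4, while the others could not be tested there. Of the 83 list tests without a call, 1 to 11 passed in each of these settings other than an estimated correlation, and up to 12 with a library left out (KO tumor 3), among them oxidative phosphorylation and cell cycle between KO and WT tumors. Depth is unknown, so its limits cannot be given.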

Other observations

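The partial correlation of gene span given transcript length was chosen after the correlations of the change with both lengths were seen, and the removal of trends after the data were seen. Lists with too few members for a test gave single values. Jchain, the joining chain of antibodies, was 1.71 in WT liver, 3.07 in KO liver, 34.9 in WT tumors and 9.64 in KO tumors, and Cd79b, of the B cell receptor, 0.31, 1.24, 1.66 and 2.19. Among adipose and muscle genes Cfd was 5.26, 1.32, 5.65 and 0.50, Adrb3 1.98, 6.83, 3.69 and 4.99, and Mylpf 0.60, 1.33, 0.78 and 1.27. No exocrine pancreas gene reached the filter.

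Genes changed in KO normal liver may in part reflect the length of genes, because the change fell with gene span across 10373 genes (Spearman's rho -0.276, 95% interval -0.294 to -0.258), and Setd2 acts along transcribed genes. A bias with transcript length and an effect of Setd2 on long genes cannot be told apart, since removing the trends with transcript length within the 6 normal livers kept 60.7% of the calls, and the partial rho was -0.092 (-0.111 to -0.072) for span given transcript length and -0.234 for transcript length given span. Within a tissue, rho of a library's deviation with transcript length was -0.318, -0.232 and -0.258 in KO livers and 0.369, 0.121 and 0.323 in WT livers, but 0.25, -0.095 and -0.262 in KO tumors and 0.163, -0.013 and -0.059 in WT tumors, so the trend also varied between libraries of a genotype. GC content as the whole cause is argued against, as 82.7% of calls stayed with its trend removed. Calls were not enriched near the targeted locus, with 1.67% within 20 Mb of Setd2 against 1.95% of other genes. Strain variants carried along with the locus stay open, since this window could not hold most of the calls and variants may act on distant genes. Transcription running past gene ends into a neighbor stays open, since genes that rose 2-fold lay within 10 kb downstream of an expressed gene with an odds ratio of 1.22 (0.84 to 1.74), an interval that includes both 1 and 1.5, against 0.89 (0.58 to 1.33) for 10 kb upstream, and the test missed more of these genes than of others (182 of 240 or 75.8% were placed, against 88.9% of all).

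The splits of 6 libraries were too few for a share under 0.1, with 1 of 10 splits reaching the real count in each 2-group comparison, 2113 against at most 2 in KO normal liver, 1981 against 0 for tumor in WT and 1664 against at most 1 for tumor in KO.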
